A study of Rattus norvegicus with 18 samples.

How the data were processed

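Affymetrix rat arrays were hybridised with biotin-labelled cRNA from pools of total RNA, each made of equal masses from 6 rats, per the labels' protocols. The deposited values were probe set intensities on a linear scale, 31099 probe sets on each of 18 arrays, made with the MAS5 algorithm per the submitters' processing notes. The version, the background settings, the detection calls and the scaling target were not given in the sources used here. From the values, the mean of each array after trimming 2% at each end lay between 99.66 and 99.74 and the median signal between 32.1 and 37.1, so the arrays had been scaled to a common level. Between 1114 and 2012 probe sets per array lay under a signal of 1. Sample labels give recovery as 72 h of deprivation and 6 h of sleep, while the treatment text can be read as 6 h after 78 h; the sample labels are used.

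Signals were raised to a floor of 1, log2-transformed and not normalized further. Control probe sets (57) were left out, the arrays of 1 pool were averaged, and the lowest 40% of the 31042 remaining probe sets by mean log2 value (a signal under 19.7) were left out, which kept 18625. Folds are on this log2 scale. For the probe sets in the file, 20832 had 1 gene symbol, 436 several and 9831 none in the platform annotation, and names were given only to those with 1. Symbols were updated through gene identifiers, which matched for 20764 probe sets and changed 0 symbols. Among the kept probe sets 14113 had 1 symbol, for 10294 genes. Of 2853 genes with several kept probe sets, between 1383 and 1567 had probe sets of both signs in a comparison.

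The test was limma's lmFit and eBayes with an intensity trend (limma 3.58.1, R 4.3.3), on a means model of all 6 groups, which share an estimate of the spread because each group has 2 pools (6 residual and 3.78 prior degrees of freedom). Differences between structures and interactions were tested on the hippocampal minus neocortical difference of the 6 animal pools, since both structures came from the same rats (3 residual and 4.13 prior degrees of freedom). A probe set was called at a Benjamini-Hochberg adjusted p under 0.05. Within a structure the pools are separate sets of animals, and each neocortical pool shares its 6 rats with a hippocampal pool. The estimate of the spread over all 6 groups takes the 12 pools as independent, although the correlation within the 6 animal pools was 0.24. The p-values of limma for single probe sets measure the spread between pools of 6 rats. Figures were drawn with matplotlib 3.10.9 and numpy 2.4.6 under Python 3.11.15.

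The number of the biological replicate names a set of rats in the series design, and set 1 was handled with an extra technical pool. It was therefore treated as a batch, present in every group, although the labels do not state that sets of different groups shared a day or litter. Deviations of same-numbered pools from their group means correlated at 0.539 to 0.682 within a structure and at 0.182 to 0.387 between structures. With only 2 pools per group these correlations come from the data and not from the labels. Results are given with the set as a fixed block in each structure where that changes a call or a count (4 residual and 7.58 prior degrees of freedom), and list medians and leading genes are given within each set. Within a set each group has 1 pool, so no test was made there.

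Lists of genes were tested with camera at a preset correlation of 0.01 on 1 probe set per gene, the one with the highest mean, over 26 lists of at least 5 measured genes and 6 comparisons, adjusted together. They cover activity-regulated, circadian clock, glucocorticoid-responsive, cholesterol synthesis, inflammation, heat shock, endoplasmic reticulum chaperone, mitochondrial, ribosomal, glutamate receptor, presynaptic, GABA, neuropeptide, neuromodulator receptor and oxidative stress genes. They also cover markers of astrocytes, microglia, oligodendrocytes and their precursors, endothelium, choroid plexus, meninges and of hippocampal, neocortical, striatal and thalamic neurons. Every list was also tested with camera at an estimated correlation and with fry. At the preset correlation camera takes genes as nearly independent, so a list p-value rests largely on the spread between genes. A very small one does not show that the shift exceeds the spread between pools.

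For each comparison the genes to be named were the 8 largest rises and falls past the threshold with pools that do not overlap, or the 5 smallest p where nothing passed, up to 4 called members of each list or the member with the smallest p, and for the structures the 5 largest each way. Other list members given as examples, and Hbb, Hba-a3 outside the recovery hippocampal formation, Alas2, Ttr and the second probe sets of Gpd1 and Bdnf, were chosen after their values were seen. The grouping, the tests, the lists, this rule and the alternatives were fixed before the data were examined, with these exceptions added later: fits without the hippocampal pools of set 2, median centring of the list tests, list tests of the differences between structures, and the block for shared and returning calls. Alternatives were quantile normalization, median centring, a pseudocount of 16, no filter or a filter at 60%, each technical replicate alone, no intensity trend, an adjusted p under 0.1, a fold of at least 1.3, random blocks for the pool and for the animal pool, array weights, fits on fewer pools, leaving out each pool, and for lists the mean of all probe sets of a gene.

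The procedure was tested on simulated data built from the real probe sets for deprivation against control in the neocortex (18625 probe sets). The simulated pools carried the same set effect in every group of a structure, and independent noise with the spread left after the block. A gain from the block was therefore built in. Of 100 probe sets changed 2-fold, 42% were recovered without and 75% with the block, and of 100 changed 4-fold, 90% and 99%. Among the unchanged probe sets of that simulation 0 were called without and 7 with the block.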

Results

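The transcriptomes of the neocortex and of the hippocampal formation were measured in male Sprague-Dawley rats with different amounts of paradoxical (rapid eye movement) sleep. Paradoxical sleep was prevented with the flowerpot method, in which a rat on a small platform over water is woken by the loss of muscle tone that comes with this sleep state. Control rats stayed in the home cage, deprived rats spent 78 h on the platforms, and recovery rats spent 72 h on the platforms followed by 6 h in which sleep was allowed. All rats were killed at the same clock time. Each of the 3 states held 12 rats in 2 sets of 6, and RNA of the right neocortex and of the right hippocampal formation was pooled within each set. The 18 arrays therefore measured 12 pools, with n = 2 pools in each of the 6 groups. Set 1 was pooled and hybridised independently on 2 arrays per group, which were averaged, and set 2 on 1 array. The number of arrays limits the precision.

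The pools separated by structure first and by set next, with the sleep states close together. The first principal component held 48.3% of the variance and the second 19.1%. On the first component the neocortical pools lay between -26.35 and -20.71, the hippocampal pools of set 1 between 37.94 and 46.57, and the hippocampal pools of set 2 between 0.2995 and 10.01. The median correlation between arrays was 0.9796 for technical replicates, 0.9779 for different states of the same structure and set, and 0.9682 for the same group in different sets. The 3'/5' signal ratio of beta-actin, a measure of RNA integrity, was 2.64 ± 0.048 in control neocortex, 2.67 ± 0.447 in deprived neocortex and 3.00 ± 0.242 in recovery neocortex (SD, n = 2 pools). It was 2.47 ± 0.0711, 2.45 ± 0.0165 and 2.36 ± 0.0392 in the hippocampal groups in the same order (SD, n = 2 pools).

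**Figure D1:**
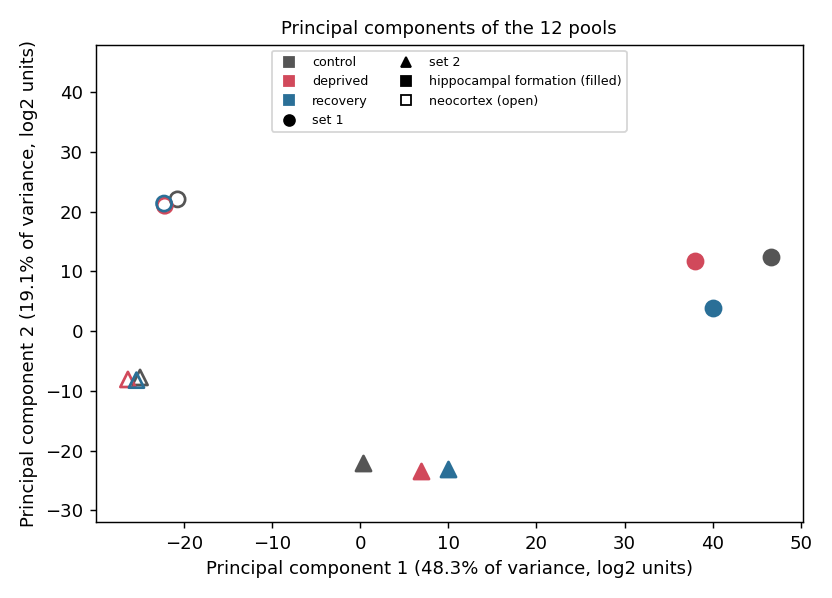
Position of the 12 pools on principal component 1 (48.3% of the variance) and component 2 (19.1%), in log2 units, computed from the probe sets kept. Color gives the sleep state, filled markers the hippocampal formation, open markers the neocortex, circles set 1 and triangles set 2, and pools of a structure and set lie together whatever their sleep state.

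The 2 structures were compared first, as a check of the labels. Of the 14 hippocampal neuron markers measured, 13 were higher in the hippocampal formation and 1 did not pass the test, with a median log2 difference of 1.14. Fibcd1 was higher (adjusted p = 5.9e-05, 6 pools per structure), with a mean log2 signal of 6.90 against 3.71 in the neocortex, as were Pkp2, a desmosomal protein (6.81 ± 0.0388 against 4.385 ± 0.44, SD, adjusted p = 0.000153), the transcription factor gene Lhx9 (5.64 against 3.23) and Prss35 (6.03 against 3.96). Of the 19 neocortical neuron markers, 9 were lower in the hippocampal formation, 2 were higher and 8 did not pass. Lamp5, Cux2 and Mef2c were 3.07-fold, 3.02-fold and 2.89-fold lower, and Foxp2, a transcription factor of deep-layer neurons, was lower as well (3.86 against 6.92 in the neocortex, adjusted p = 0.000587). Outside these lists, Nts, the neurotensin precursor, was 8.26-fold higher, and the serotonin receptor gene Htr5b (6.50 against 3.60) and the neurotrophin gene Ntf3 (6.95 against 4.28) were higher. The adenosine receptor gene Adora2a (3.31 against 6.33), the respiratory chain gene Cox6a2 (2.85 against 5.80), Olr59 (3.48 against 6.24) and Trim54 (3.54 against 6.05) were lower. For each gene given with a pair of log2 signals the lower one lay under 4.3, the level of the filter on dim probe sets, or for Pkp2 within 1 SD of it, so the direction is given and the size of the fold is not settled.

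The lists of striatal and of meningeal markers also differed between the structures, and whether neighbouring tissue in the samples contributed was not tested. Of the 13 striatal neuron markers, among them Adora2a, 12 were lower in the hippocampal formation (median -1.53). Of the 18 meningeal and fibroblast markers, 15 were lower and 2 higher (median -0.89). Among 21 glucocorticoid-responsive genes 9 were higher and 2 lower, among 20 clock genes 7 were lower, and among 22 genes of GABA signalling 5 were higher and 9 lower. In all, 3700 of 18625 probe sets passed limma's test on the differences within the 6 animal pools, 1751 higher and 1949 lower in the hippocampal formation. Adding the set as a block gave 8006, which included all 3700. Leaving out 1 animal pool gave between 1625 (without the deprived pool of set 1) and 4507 calls, with 1790 without the recovery pool of set 1, 2171 without the control pool of set 1 and 2338 without the deprived pool of set 2.

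In the neocortex, deprivation was compared with the home cage to ask which transcripts differed after the loss of paradoxical sleep. Glucocorticoid-responsive genes rose as a group: of 21 measured, 20 were above control and 1 below, with a median log2 change of 0.25 (camera, adjusted p = 5.32e-12). The value for this list was adjusted p = 0.0607 with an estimated correlation. Gpd1, a glycerol-3-phosphate dehydrogenase, was 1.97-fold higher (log2 change 0.98, SE 0.143, n = 2 pools each, adjusted p = 0.945), from a log2 signal of 7.51 ± 0.296 to 8.49 ± 0.0609 (SD). Sgk1, a kinase induced by glucocorticoids, was 1.72-fold higher (log2 change 0.78, SE 0.148, adjusted p = 1). Sult1a1, Cdkn1a and Fkbp5 had log2 changes of 0.80, 0.58 and 0.35.

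Activity-regulated genes, which neurons transcribe in response to firing, rose too in the deprived neocortex. Of 32 measured, 29 were above control and 3 below, with a median log2 change of 0.25 (adjusted p = 2.08e-16, and adjusted p = 0.0341 with an estimated correlation). Arc, which encodes a synaptic protein made in active neurons, was 1.91-fold higher (log2 change 0.93, SE 0.199, adjusted p = 1), and Sik1, Gadd45b, Fos and Egr2 had log2 changes of 1.07, 1.02, 0.95 and 0.78, with the size for Sik1 not settled because its control signal (log2 3.93) lay under the filter level of 4.3. Neuropeptides and trophic factors rose, with 18 of 24 above control and a median of 0.067 (adjusted p = 0.0361, and adjusted p = 0.487 with an estimated correlation). Crh, the corticotropin-releasing hormone gene, had the smallest p of this list, with a log2 change of 0.59 (SE 0.309). Outside the lists, Sc5d, a sterol desaturase of cholesterol synthesis, had a log2 change of 0.78 (SE 0.181) and the sorting nexin gene Snx4 one of -0.45 (SE 0.108), both with adjusted p = 1.

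No single probe set passed in that comparison. By limma's test 0 of 18625 were called, and 207 had an unadjusted p under 0.05, against 931.2 by chance. A count so far below chance goes with p-values that are too large, as this fit leaves the difference between the sets in its spread. The same holds for the other comparisons of sleep states, so 0 calls there does not show a lack of response. Under a block for the set, 1070 had an unadjusted p under 0.05 and 2 probe sets were called, those of Gpd1 (adjusted p = 0.00826) and Arc (adjusted p = 0.0113), both higher after deprivation. Log2 changes within set 1 and set 2 were 1.15 and 0.813 for Gpd1 and 0.907 and 0.961 for Arc. With all arrays kept separate and the pool as a random block, Gpd1 (adjusted p = 0.00221) and Sgk1 (adjusted p = 0.0236) were called. That fit takes in both arrays of each set 1 pool, at a correlation within pools of 0.3. Its p-values therefore rest partly on technical replicates. Adjusted over the list alone, Arc passed among activity-regulated genes and Sgk1 and Gpd1 among glucocorticoid-responsive genes, against 0 over all probe sets. With the block, 11 activity-regulated and 6 glucocorticoid-responsive genes passed when adjusted over the list alone, all higher. List medians in set 1 and set 2 were 0.18 and 0.292 for activity-regulated genes, 0.0442 and 0.0976 for neuropeptides, and 0.361 and 0.143 for glucocorticoid-responsive genes. The glucocorticoid median was 0.153 without the deprived pool of set 1 and 0.388 without that of set 2, still called. The neuropeptide call ended without the control pool of set 1 (adjusted p = 0.429) or the deprived pool of set 2 (adjusted p = 0.484).

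**Figure D2:**
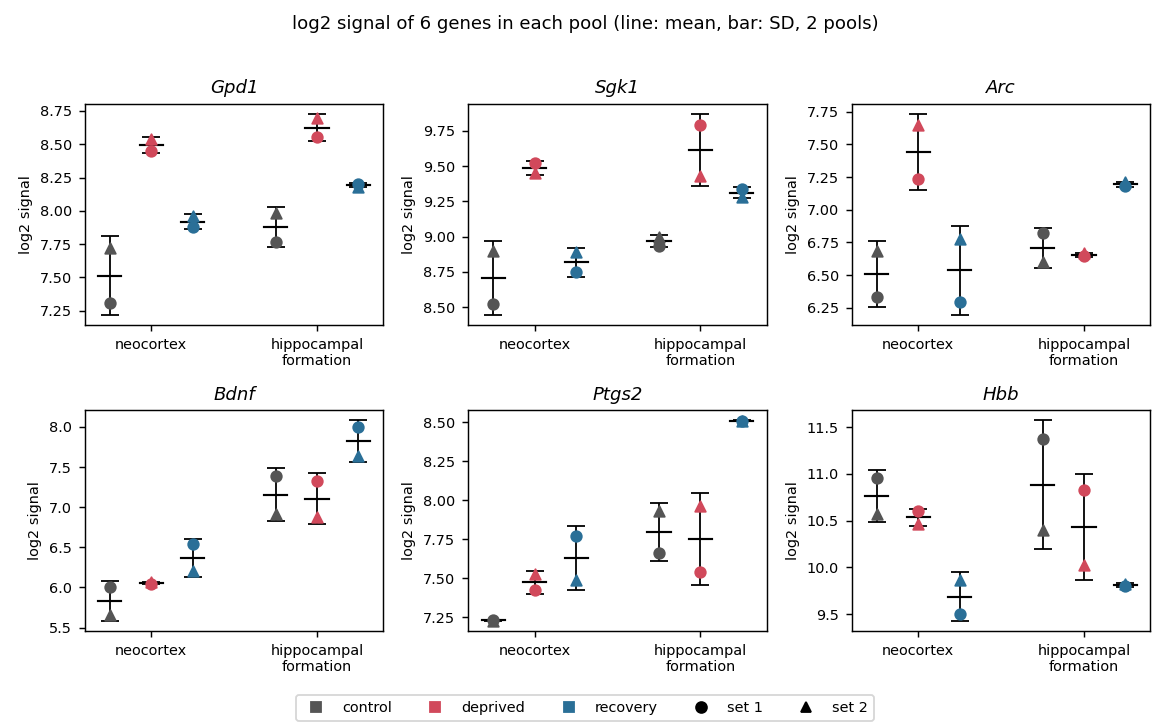
Log2 signal of Gpd1, Sgk1, Arc, Bdnf, Ptgs2 and Hbb in each of the 12 pools, by structure and sleep state, with the mean (line) and SD (bar) of 2 pools and a scale of its own for each gene. Gpd1 and Sgk1 lie highest in the deprived pools of both structures, with means of 8.49 and 8.62 for Gpd1, and Hbb lies lowest in the recovery pools, with means of 9.69 and 9.81.

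In the hippocampal formation, glucocorticoid-responsive genes rose after deprivation as well. All 21 measured were above control, with a median log2 change of 0.23 (adjusted p = 4.3e-12, and adjusted p = 0.0607 with an estimated correlation). Gpd1 was 1.68-fold higher (log2 change 0.74, SE 0.143, n = 2 pools each, adjusted p = 1) and Sgk1 1.56-fold higher (0.64, SE 0.148, adjusted p = 1). Pdk4, a kinase that inhibits pyruvate dehydrogenase, and Sult1a1 had log2 changes of 0.93 and 0.57. The activity-regulated list was not called there, with a median of -0.0064 (adjusted p = 0.479).

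Genes of cholesterol synthesis fell in the deprived hippocampal formation, with 20 of 24 below control and a median of -0.10 (adjusted p = 0.000225, and adjusted p = 0.346 with an estimated correlation). Mvd, Sqle and Tm7sf2, enzymes of the pathway, had log2 changes of -0.35, -0.29 and -0.24. Inflammation and innate immune genes fell, with 15 of 16 below control and a median of -0.17 (adjusted p = 0.004, and adjusted p = 0.812 with an estimated correlation), among them Irf7 at -0.37 and Ifit2 at -0.30. Cytosolic heat shock proteins rose, with 13 of 17 above control and a median of 0.076 (adjusted p = 0.0143, and adjusted p = 0.69 with an estimated correlation), with Cryab at 0.37. Oligodendrocyte and myelin markers fell, with 15 of 21 below control and a median of -0.095 (adjusted p = 0.0138, and adjusted p = 0.934 with an estimated correlation). Striatal neuron markers fell, with 12 of 13 below control and a median of -0.15 (adjusted p = 0.0361, and adjusted p = 0.934 with an estimated correlation). Among single genes, Gpatch4, Cmip and Usp54 had log2 changes of 1.93 (SE 0.422), -1.04 (SE 0.225) and 0.45 (SE 0.103), each with adjusted p = 1. The red cell genes Hbb, Hba-a3 and Alas2 had log2 changes of -0.45 (SE 0.32), -0.61 (SE 0.283) and -0.55 (SE 0.443) beside the lists, each with adjusted p = 1 and below 0 in both sets. The size is not settled for Gpatch4 and Cmip, whose log2 signals of 3.46 in control and 4.18 after deprivation lay under the filter level of 4.3.

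For deprivation in the hippocampal formation limma called 0 of 18625 probe sets, and 204 had an unadjusted p under 0.05. Under a block for the set it called 0 too (1106 unadjusted, smallest adjusted p = 0.102). Sgk1 and Gpd1 passed adjusted over the list alone, against 0 over all probe sets, and 7 glucocorticoid-responsive genes did with the block. Medians in set 1 and set 2 were 0.381 and 0.131 for glucocorticoid-responsive genes, -0.174 and -0.0637 for cholesterol synthesis, -0.134 and -0.253 for inflammation, 0.0832 and 0.146 for heat shock proteins, -0.242 and 0.0451 for oligodendrocyte markers and 0.0931 and -0.368 for striatal markers. The cholesterol call ended without the control pool of set 1 (adjusted p = 0.137) or the deprived pool of set 1 (0.119), and the inflammation call without the control pool of set 1 (0.275) or the deprived pool of set 2 (0.854), and with no filter on dim probe sets (0.0586). The heat shock call ended without the control pool of set 2, where the median was -0.10 (adjusted p = 0.896), or the deprived pool of set 1 (0.516). The oligodendrocyte call ended without the deprived pool of set 2 (adjusted p = 0.249) and its median was 0.0645 without the control pool of set 1. The striatal call ended without either deprived pool (adjusted p = 0.116 and 0.277) and its median was 0.0766 without the control pool of set 2. The striatal call also ended with no filter (adjusted p = 0.154) and with the mean of all probe sets of each gene (0.241). Without the hippocampal pools of set 2, a choice made after their separate position was seen, the calls of the heat shock (adjusted p = 0.413) and inflammation (0.542) lists ended and the striatal median was 0.0931. With the block, endoplasmic reticulum chaperones were called higher (median 0.070, 0.0537 in set 1 and 0.116 in set 2, adjusted p = 0.00977, and adjusted p = 0.587 with an estimated correlation). Presynaptic genes were called lower with it (median -0.080, adjusted p = 0.044, and adjusted p = 0.703 with an estimated correlation), although the set medians of -0.0918 and 0.0388 had opposite signs. Both lists had adjusted p = 0.0505 without the block.

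Recovery was compared with the home cage to ask what differed 6 h after the end of deprivation. In the neocortex, activity-regulated genes were above control: 25 of 32 were higher and 7 lower, and the list rose by a median of 0.20 (adjusted p = 2.2e-08, and adjusted p = 0.0607 with an estimated correlation). Sik1, Egr2 and the neurotrophin gene Bdnf had log2 changes of 0.95, 0.72 and 0.54, while Arc was at 0.028 (SE 0.199). The size for Sik1 is not settled, since its control signal of 3.93 lay under the filter level of 4.3. Neuropeptides and trophic factors rose, with 16 of 24 above control and a median of 0.15 (adjusted p = 0.00128, and adjusted p = 0.242 with an estimated correlation). Scg2, the secretogranin II gene, which belongs to both lists, had a log2 change of 0.44 (SE 0.112, n = 2 pools each, adjusted p = 1). The glucocorticoid-responsive list was not called, with a median of 0.051 (adjusted p = 0.595).

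Circadian clock genes fell in the recovery neocortex, with 16 of 20 below control and a median of -0.17 (adjusted p = 0.00022, and adjusted p = 0.0607 with an estimated correlation). Per1, a core clock gene, and Rora, a nuclear receptor of the clock, had log2 changes of -0.53 and -0.54. Inflammation and innate immune genes fell, with 15 of 16 below control and a median of -0.23 (adjusted p = 0.00164, and adjusted p = 0.762 with an estimated correlation). Irf7 and the complement gene C3 had log2 changes of -0.48 and -0.94. Microglia markers fell, with 10 of 15 below control and a median of -0.23 (adjusted p = 0.0379, and adjusted p = 0.95 with an estimated correlation), with Cx3cr1 at -0.30. Among single genes, Sncg, the gamma-synuclein gene, was 1.91-fold higher (log2 change 0.93, SE 0.24), the translation initiation factor gene Eif3c had a log2 change of -0.55 (SE 0.136), Myh1 one of 0.44 and Sertm1 one of 0.51, each with adjusted p = 1. The haemoglobin gene Hbb was 2.11-fold lower (log2 change -1.08, SE 0.32, adjusted p = 1), and the choroid plexus gene Ttr had a log2 change of 1.46 (SE 1.37). Within set 1 and set 2 the changes were -1.45 and -0.702 for Hbb and 0.252 and 2.66 for Ttr. By their set medians, given below, the inflammation and microglia lists were below control in set 1 only. The beta-actin ratio was 3.00 in this group, while the 3'/5' ratio of Gapdh was 1.08 and 1.17 in recovery and 1.08 and 1.12 in control (set 1 and set 2).

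For recovery against control in the neocortex limma called 0 of 18625 probe sets, and 209 had an unadjusted p under 0.05. The count with the set as a block was likewise 0 (1078 unadjusted, smallest adjusted p = 0.325). Adjusted over the list alone, 0 activity-regulated genes passed, and 8 did with the block, 7 higher and Per1 lower. Medians in set 1 and set 2 were 0.248 and 0.174 for activity-regulated genes, 0.0462 and 0.113 for neuropeptides, -0.199 and -0.202 for clock genes, -0.538 and 0.072 for inflammation and -0.393 and 0.126 for microglia. The clock call ended without the recovery pool of set 1 (median -0.061, adjusted p = 0.0614), and the neuropeptide call without the control pool of set 1 (adjusted p = 0.127) or the recovery pool of set 2 (0.154). Without the control pool of set 1 the inflammation median was 0.0418 and the microglia median 0.261, and the microglia call also ended without the recovery pool of set 2 (adjusted p = 0.613). Without a filter on dim probe sets the inflammation (adjusted p = 0.101) and microglia (0.0629) calls ended. With the block, choroid plexus and ependymal markers were called higher (median 0.45, 0.256 in set 1 and 0.845 in set 2, adjusted p = 0.0438, against 0.23 without it, and adjusted p = 0.767 with an estimated correlation).

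In the recovery hippocampal formation activity-regulated genes rose, with 29 of 32 above control, 3 below and a median of 0.31 (adjusted p = 3.19e-18, and adjusted p = 0.0341 with an estimated correlation). Ptgs2, the gene of cyclooxygenase-2, was 1.64-fold higher (log2 change 0.72, SE 0.159, n = 2 pools each, adjusted p = 1), from 7.80 ± 0.188 to 8.51 ± 0.000404 (SD). The nuclear receptor gene Nr4a3 had a log2 change of 0.47 (SE 0.111), and Fos, Inhba, Egr2 and Klf10 had 0.84, 0.79, 0.72 and 0.71. Neuropeptides and trophic factors rose, with 15 of 24 above control and a median of 0.061 (adjusted p = 0.0361, and adjusted p = 0.487 with an estimated correlation), and Bdnf was at 0.67. Glucocorticoid-responsive genes rose, with 16 of 21 above control and a median of 0.19 (adjusted p = 0.0042, and adjusted p = 0.487 with an estimated correlation), with Sgk1 at 0.34 and Gpd1 at 0.31.

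Meningeal and fibroblast markers fell in the recovery hippocampal formation, with 15 of 18 below control and a median of -0.26 (adjusted p = 0.000101, and adjusted p = 0.645 with an estimated correlation). The collagen gene Col1a1, Ogn and Fmod, genes of the extracellular matrix, had log2 changes of -1.32, -0.72 and -0.52, with Col1a1 dim in recovery (log2 signal 3.97, under the filter level of 4.3). Genes of cholesterol synthesis fell, with 22 of 24 below control and a median of -0.087 (adjusted p = 0.0263, and adjusted p = 0.645 with an estimated correlation), with Dhcr7 at -0.30 and Sqle at -0.25. Among single genes, Sncg was 2.23-fold higher (log2 change 1.16, SE 0.24), the haemoglobin gene Hba-a3 2.29-fold lower (-1.19, SE 0.283) and Tshz3 1.35-fold lower (-0.43, SE 0.104), each with adjusted p = 1. Hbb was 2.10-fold lower (SE 0.32, adjusted p = 1) and Ttr had a log2 change of -1.60 (SE 1.37), beside the changes of the lists.

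The same test in the hippocampal formation called 0 of 18625 probe sets by limma, and 282 had an unadjusted p under 0.05. A block for the set left the count at 0 (1363 unadjusted, smallest adjusted p = 0.0564). Nr4a3 and Ptgs2 passed adjusted over the list alone, against 0 over all probe sets, and 16 activity-regulated genes did with the block, all higher. Medians in set 1 and set 2 were 0.36 and 0.205 for activity-regulated genes, 0.108 and 0.0834 for neuropeptides, 0.179 and 0.111 for glucocorticoid-responsive genes, -0.43 and -0.236 for meningeal markers and -0.103 and -0.0702 for cholesterol synthesis. The glucocorticoid call ended without the control pool of set 1 (adjusted p = 0.188), without the recovery pool of set 1 (0.119) and with no filter on dim probe sets (0.143), and its median was 0.0784 without the control pool of set 2. The meningeal call ended without the control pool of set 2 (adjusted p = 0.205) or the recovery pool of set 1 (0.176). The cholesterol call ended without any of the 4 pools compared in turn (adjusted p = 0.399 and 0.0576 without the control pools, 0.149 and 0.135 without the recovery pools) and with the mean of all probe sets (0.0699). The neuropeptide call ended without either control pool (adjusted p = 0.109 and 0.315), without the recovery pool of set 1 (0.395), with no filter (0.137) and with the mean of all probe sets (0.0623). Without the hippocampal pools of set 2 the cholesterol and neuropeptide calls ended, each at adjusted p = 0.0584. With the block, microglia markers were called lower (median -0.12, adjusted p = 0.0158, against 0.18 without it, and adjusted p = 0.786 with an estimated correlation), with medians of -0.275 in set 1 and 0.00636 in set 2. Presynaptic genes were also called lower with it (median -0.053, adjusted p = 0.0418, against 0.114, and adjusted p = 0.703 with an estimated correlation), with medians of -0.101 and -0.00495.

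Recovery was also compared directly with deprivation. In the neocortex glucocorticoid-responsive genes fell, with 19 of 21 lower in recovery, 2 higher and a median of -0.26 (adjusted p = 1.61e-11, and adjusted p = 0.0607 with an estimated correlation). A probe set of Gpd1 other than the one above was 2.28-fold lower (log2 change -1.19, SE 0.213, n = 2 pools each, adjusted p = 1), and the one above had -0.57 (SE 0.143). Sgk1 was 1.59-fold lower (-0.67, SE 0.148) and Ddit4, an inhibitor of mTOR signalling, had a log2 change of -0.46 (SE 0.133). Activity-regulated genes fell too, with 21 of 32 below deprivation and a median of -0.097 (adjusted p = 0.0326, and adjusted p = 0.532 with an estimated correlation). Arc was 1.87-fold lower (log2 change -0.91, SE 0.199, adjusted p = 1). Clock genes fell, with 15 of 20 lower and a median of -0.10 (adjusted p = 0.00405, and adjusted p = 0.143 with an estimated correlation), with Rora at -0.61 and Per1 at -0.56. Sncg was 2.14-fold higher (1.10, SE 0.24) and the chromatin remodelling gene Smarcc2 had a log2 change of -1.32 (SE 0.32), each with adjusted p = 1. The size for Smarcc2 is not settled, since its log2 signal of 3.50 in recovery lay under the filter level of 4.3. The red cell genes Hbb, Hba-a3 and Alas2 had log2 changes of -0.85 (SE 0.32), -0.67 (SE 0.283) and -1.01 (SE 0.443) beside these lists, each with adjusted p = 1 and below 0 in both sets. The beta-actin ratio was 2.98 and 2.35 in deprived and 3.17 and 2.83 in recovery neocortex (set 1 and set 2). Whether RNA integrity moved these lists was not tested.

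Between recovery and deprivation in the neocortex limma called 0 of 18625 probe sets, and 169 had an unadjusted p under 0.05. With that block 849 had an unadjusted p under 0.05 and 1 probe set was called, that of Arc (adjusted p = 0.0309, log2 changes -0.943 in set 1 and -0.869 in set 2). Adjusted over the list alone, Arc passed among activity-regulated genes and Sgk1, Ddit4 and Gpd1 among glucocorticoid-responsive genes, against 0 over all probe sets. With the block, 6 activity-regulated genes passed adjusted over the list alone (5 lower, and Scg2 higher), as did 8 glucocorticoid-responsive genes and 3 clock genes, all lower. Medians in set 1 and set 2 were -0.245 and -0.19 for glucocorticoid-responsive genes, -0.0786 and -0.137 for activity-regulated genes and -0.146 and -0.0328 for clock genes. The activity-regulated call ended without the deprived pool of set 2 (adjusted p = 0.432), without either recovery pool (0.0915 and 0.144) and with no filter on dim probe sets (0.133). The clock call ended without the deprived pool of set 2 (adjusted p = 0.0922) or the recovery pool of set 1 (0.183), and the glucocorticoid median was -0.404 without the deprived pool of set 2. With the block, cytosolic ribosomal proteins were called higher (median 0.054, 0.0238 in set 1 and 0.0635 in set 2, adjusted p = 0.00498, against 0.233 without it, and adjusted p = 0.767 with an estimated correlation).

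In the hippocampal formation activity-regulated genes rose from deprivation to recovery, with 26 of 32 higher, 6 lower and a median of 0.25 (adjusted p = 1.13e-13, and adjusted p = 0.038 with an estimated correlation). Ptgs2 was 1.69-fold higher (log2 change 0.76, SE 0.159, n = 2 pools each, adjusted p = 1), and Egr2, Bdnf, Klf10 and Egr4 had log2 changes of 0.88, 0.72, 0.71 and 0.59. A Bdnf probe set of lower signal was at 0.17 (SE 0.221). Glucocorticoid-responsive genes fell, with 16 of 21 lower and a median of -0.18 (adjusted p = 0.00188, and adjusted p = 0.474 with an estimated correlation), with Gpd1 at -0.43 (SE 0.143). Neuropeptides and trophic factors rose, with 17 of 24 higher and a median of 0.099 (adjusted p = 0.0326, and adjusted p = 0.487 with an estimated correlation). Oligodendrocyte and myelin markers rose, with 16 of 21 higher and a median of 0.10 (adjusted p = 0.00874, and adjusted p = 0.934 with an estimated correlation), with Opalin at 0.30 and Fa2h at 0.27. Among single genes, Sncg had a log2 change of 1.03 (SE 0.24), the synaptic scaffold gene Caskin1 -0.71 (SE 0.156), the transporter gene Slc4a11 0.63 (SE 0.149) and Tacc1 -0.42 (SE 0.114), each with adjusted p = 1. Hbb, Hba-a3 and Alas2 had log2 changes of -0.62, -0.59 and -0.90 beside the lists, each with adjusted p = 1 and below 0 in both sets. Alas2 was dim in recovery (log2 signal 4.11, under the filter level of 4.3).

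Between recovery and deprivation in the hippocampal formation limma called 0 of 18625 probe sets, and 301 had an unadjusted p under 0.05. A block for the set again gave 0 (1334 unadjusted, smallest adjusted p = 0.0862). Egr1, Egr2, Egr4, Nr4a1, Bdnf, Ptgs2 and Klf10 passed adjusted over the list alone, against 0 over all probe sets, and 12 activity-regulated genes did with the block, all higher. Medians in set 1 and set 2 were 0.345 and 0.149 for activity-regulated genes, 0.134 and 0.089 for neuropeptides, -0.233 and -0.0689 for glucocorticoid-responsive genes and 0.229 and -0.0352 for oligodendrocyte markers. The activity-regulated median was 0.149 without the recovery pool of set 1 and 0.371 without that of set 2, still called. The glucocorticoid call ended without the deprived pool of set 1 (median -0.0040, adjusted p = 0.519) or the recovery pool of set 2 (-0.135, adjusted p = 0.135), and its median was -0.315 without the deprived pool of set 2. The neuropeptide call ended without either deprived pool (adjusted p = 0.176 and 0.113), without the recovery pool of set 1 (0.404), with no filter (0.0944) and with the mean of all probe sets (0.0785). The oligodendrocyte call ended without the deprived pool of set 2 (adjusted p = 0.189) and with no filter (0.06), and its median was -0.0529 without the recovery pool of set 1. With the block, choroid plexus markers were called lower (median -0.80, adjusted p = 0.00871, against 0.142 without it, and adjusted p = 0.715 with an estimated correlation), with medians of -1.73 in set 1 and -0.0511 in set 2. Astrocyte markers were called lower too (median -0.064, adjusted p = 0.0466, against 0.126, and adjusted p = 0.767 with an estimated correlation), with medians of -0.09 and -0.121.

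**Figure D3:**
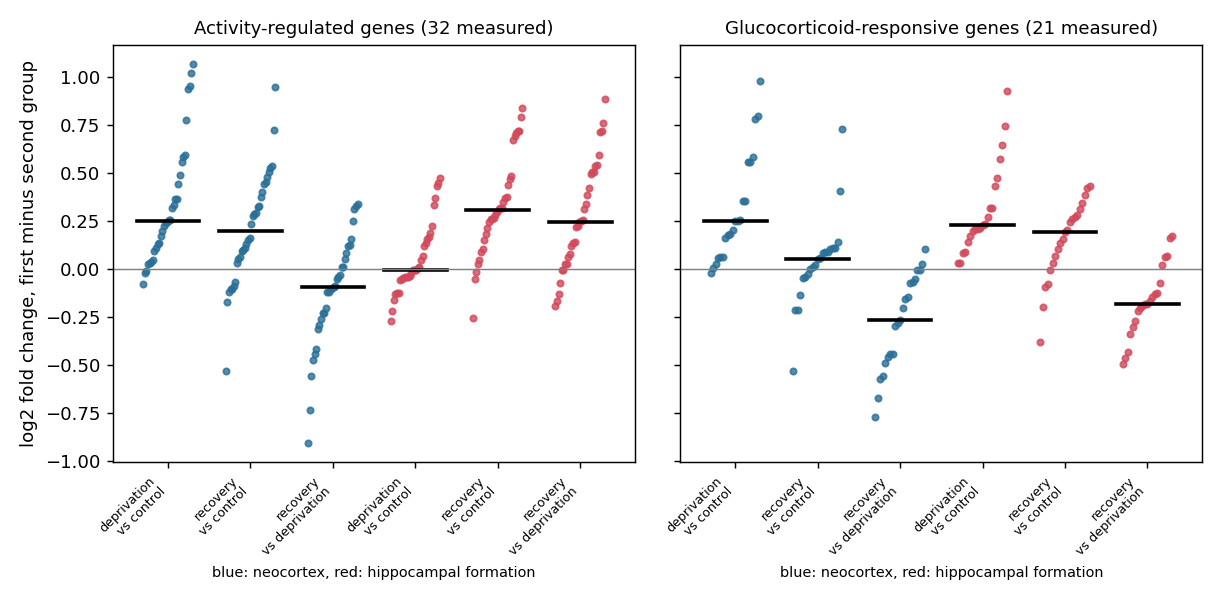
Log2 fold change of each measured member of the activity-regulated list (32 genes) and the glucocorticoid-responsive list (21 genes) in the 6 comparisons, first group minus second, with the median as a line, neocortex in blue and hippocampal formation in red. The activity-regulated median is 0.25 in the deprived neocortex and -0.0064 in the deprived hippocampal formation, and the glucocorticoid-responsive medians there are 0.25 and 0.23.

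Whether the structures responded differently was tested on the hippocampal minus neocortical difference of each animal pool. Between deprivation and recovery, Arc had a difference of 1.45 on the log2 scale (SE 0.265, adjusted p = 1), with 1.48 in set 1 and 1.41 in set 2, and Klf10 one of 1.03 (SE 0.169, adjusted p = 1). The named genes Nckap5l, Ints15 and Egr1 had differences of 1.28, 0.96 and 0.59, with Nckap5l dim in the deprived hippocampal formation at a log2 signal of 4.25. For deprivation against control, the smallest p belonged to Phf14 (0.84), Ints15 (-0.81), Uck2 (0.90), Dnajb5 (-0.64) and Vstm5 (-1.05, dim in the deprived hippocampal formation at a log2 signal of 3.97), and for recovery against control to Sv2b (1.52), Cdk5rap3 (-1.01), Rnf227 (0.59), Eif3c (0.76) and Klf10 (0.66), each with adjusted p = 1. In each of these 3 tests limma called 0 of 18625 probe sets, and 213 (deprivation against control), 243 (recovery against control) and 298 (recovery against deprivation) had an unadjusted p under 0.05. With the set as a block, Arc (adjusted p = 0.00906) and Klf10 (adjusted p = 0.0358) were called between recovery and deprivation, 2 probe sets in all (1082 unadjusted), and 0 by limma in the others (924 unadjusted for deprivation against control and 995 for recovery against control).

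No probe set was called in both deprivation and recovery against the shared controls in either structure, 0 by limma, and 0 in simulated groups without change. Neither comparison had a call without the block, and the simulations had a mean of 0 calls for deprivation. An overlap of 0 was therefore the only possible outcome and says nothing about shared responses. With the set as a block, 1 of the 2 probe sets called for deprivation in the neocortex, Arc, was called in the opposite direction from deprivation to recovery. These comparisons share the deprived pools, so the return is not independent of the first call: in 100 simulations without change a mean of 0.01 probe sets were called for deprivation and a mean of 0.01 returned. Those simulated pools carried the same set effect in every group and independent noise. They cannot show how often the block errs where sets are not shared between groups.

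Of the 156 tests of a list in a comparison, 26 were called. The 3 that held with an estimated correlation were those of the activity-regulated list for deprivation against control in the neocortex and for recovery against control and recovery against deprivation in the hippocampal formation. The test fry asks whether the members of a list move on balance in one direction and does not compare them with other genes. Run only without the set block, with the difference between the sets in its spread, it called 0. All 26 camera calls also held with the set as a block, where 35 were called in all. The ones added in the neocortex included endoplasmic reticulum chaperones after deprivation (median 0.086, 0.031 in set 1 and 0.0667 in set 2, adjusted p = 0.0413, against 0.126 without the block). That list had adjusted p = 0.703 with an estimated correlation and the block, and by camera 0 of the 9 added calls held with both. The activity-regulated and glucocorticoid-responsive lists share 2 measured genes, Dusp1 and Per1. Per1 is in the clock list too, and Scg2 is in both the activity-regulated and neuropeptide lists. Calls of these lists are therefore not independent, and the overlap of other pairs was not counted.

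A further 15 lists were called in no comparison without the set block, and the p-values here are without it. With it, presynaptic genes, endoplasmic reticulum chaperones, cytosolic ribosomal proteins, astrocyte markers and choroid plexus markers were called, as given above. Medians over the 6 comparisons lay between -0.031 and 0.012 for 48 genes of the mitochondrial respiratory chain (smallest adjusted p = 0.595), between -0.069 and 0.026 for 44 glutamate receptor and postsynaptic genes (0.212) and between -0.080 and 0.035 for 32 presynaptic genes (0.0505). They lay between -0.031 and 0.030 for 22 genes of GABA signalling (smallest adjusted p = 0.251), between -0.078 and 0.083 for 27 receptors of sleep-wake neuromodulators (0.12) and between -0.034 and 0.021 for 22 genes of oxidative stress defence (0.344). Cytosolic ribosomal proteins (30 genes) had medians from -0.044 to 0.054 (smallest adjusted p = 0.233) and endoplasmic reticulum chaperones (25 genes) from -0.049 to 0.086 (0.0505). Among cell type markers, medians ran from -0.064 to 0.047 for 21 astrocyte genes (smallest adjusted p = 0.126), from -0.079 to 0.012 for 17 endothelial and pericyte genes (0.269) and from -0.048 to 0.054 for 8 oligodendrocyte precursor genes (0.304). They ran from -0.044 to 0.12 for 14 hippocampal neuron genes (smallest adjusted p = 0.331), from -0.098 to 0.090 for 19 neocortical neuron genes (0.277), from -0.038 to 0.13 for 7 thalamic genes (0.261) and from -0.80 to 0.45 for 8 choroid plexus and ependymal genes (0.142). The list of blood cell markers had 2 measured genes of 10 and was not tested.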

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

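The list tests of the differences between structures, and all tests of explanations except those of array scaling for the activity-regulated and haemoglobin patterns and the splits of the structures, were chosen after the results were seen.

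Of 78 tests of a list on the hippocampal minus neocortical difference, 7 were called, 0 of them with an estimated correlation and 4 with the replicate block. The activity-regulated list moved differently in the structures from deprivation to recovery, with a median difference of 0.333 (adjusted p = 6.06e-14, and adjusted p = 0.36 with an estimated correlation). The median was 0.351 in set 1 and 0.337 in set 2, so the difference did not rest on 1 set of rats. The list was flagged on the mean of these sets, which favours such agreement, so these medians are not independent evidence. Array scaling is argued against by a median of 0.274 or more under 2 other scalings. A change in the share of neuronal RNA is argued against by the presynaptic list, whose median difference was -0.0405. No biological explanation was tested, and RNA integrity (a beta-actin ratio of 2.67 in deprived and 3.00 in recovery neocortex), the stress of the platforms and a different time course of neuronal activity in the structures all stay open.

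The same list differed between the structures for deprivation against control, with a median difference of -0.176 (-0.177 in set 1 and -0.254 in set 2, adjusted p = 7.98e-07, and adjusted p = 0.504 with an estimated correlation), and for recovery against control, with 0.134 (0.206 and 0.0848, adjusted p = 0.00698, and adjusted p = 0.867 with an estimated correlation). Choroid plexus and ependymal markers differed by -1.04 for recovery against control (-0.549 in set 1 and -1.44 in set 2, adjusted p = 0.0127, 0.171 with the block) and by -0.972 for recovery against deprivation (-1.79 and -0.17, adjusted p = 0.00698, 0.0901 with the block), and both had adjusted p = 0.892 with an estimated correlation. Glucocorticoid-responsive genes differed by 0.143 for recovery against deprivation (0.0866 in set 1 and 0.0894 in set 2, adjusted p = 0.0362, 0.0965 with the block, and adjusted p = 0.867 with an estimated correlation). Inflammation genes differed by 0.251 in that comparison (0.137 and 0.279, adjusted p = 0.00698, 0.0176 with the block, and adjusted p = 0.892 with an estimated correlation).

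Glucocorticoid-responsive genes rose after deprivation in both structures, by medians of 0.249 and 0.228 (adjusted p = 0.0607 with an estimated correlation in each), and array scaling is argued against by a median of 0.197 or more under 2 other scalings. More oligodendrocyte RNA, a cell type that expresses Gpd1, is argued against over both sets by oligodendrocyte medians of -0.0949 (SD of the members 0.166) in the hippocampal formation and -0.03 (SD 0.173) in the neocortex. Set 2 alone leaves it open, with oligodendrocyte medians of 0.0451 (SD 0.197) and 0.023 (SD 0.138) beside glucocorticoid medians of 0.131 and 0.143, and the hippocampal oligodendrocyte median was 0.0645 without the control pool of set 1. From deprivation to recovery the glucocorticoid list fell in the neocortex, with a median of -0.264 (adjusted p = 0.0607 with an estimated correlation), and in the hippocampal formation, with -0.182 (adjusted p = 0.474 with an estimated correlation). A rise from the stress of the platforms and a rise from the loss of sleep cannot be told apart, because the controls stayed in the home cage and no group met the platforms without losing sleep.

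Haemoglobin and Alas2, which red cell precursors need to make haem, were lower in recovery than in control in both structures. Array scaling is argued against by a median of -1.13 or further from 0 under 2 other scalings. A difference between the sets stays open: 12 of 12 differences (3 genes, 2 structures, 2 sets) lay below 0, the nearest to it at -0.342, but these genes were chosen because they were lower, and the recovery signal of Alas2 in the hippocampal formation (log2 4.11) lay under the filter at 4.3. Whether less blood stayed in the recovery tissue cannot be told apart from lower transcript levels in the blood. The white cell genes S100a9 and S100a8, looked at for this question, had mean log2 signals of 3.82 and 2.24, under that filter, and were not used.

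The difference between hippocampal formation and neocortex was set against the 32 splits that part the structures of each animal pool. The real split gave 3700 called probe sets and the highest of the others gave 0. These splits cannot exclude chance, since 1 of 32 is the smallest share they allow. The others also still hold the difference between the structures, which widens their spread or enters them in part.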

How the results depend on the processing

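The fits without the hippocampal pools of set 2, median centring of the list tests and the block for shared calls were chosen after the data were seen. Every other alternative listed in the methods was fixed earlier and was run. Of 221 alternative values of 13 counts, 208 stayed within 1.5 times and 13 moved, of 1485 values for 77 named genes 1476 kept direction and side of the threshold, and of 301 values for 26 called lists 192 did. Apart from the counts between the structures and of list calls, every count was 0 in the main fit. No gene named from a comparison of sleep states or its difference between structures was called there either. Such counts and genes could gain a call but not lose one, so their stability says little about robustness. Quantile normalization, median centring and the replicate block kept all 26 list calls.

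With the replicate block, that is with the sets paired across groups, 2 probe sets were called for deprivation in the neocortex, 1 for recovery against deprivation there, 2 for its difference between structures, 8006 between the structures, and 1 for a deprivation call that returned. The block changed no other count of probe sets. Of the list calls within a structure it lost none and added 9, and of the 7 on the difference between structures it kept 4. With all arrays separate and the pool as a random block, 2 were called for deprivation in the neocortex, in a fit that rests partly on technical replicates. Between the structures 2429 were called with a fold of at least 1.3, and 1625 to 4507 when an animal pool was left out. Of 26 list calls, 3 held with an estimated correlation and 0 with fry. The preset correlation takes genes as nearly independent, while the estimated one is taken from the data. All but those 3 calls therefore rest on the preset correlation. The test fry does not compare the members of a list with other genes. It was run only without the set block, where the difference between the sets stays in the spread. Its 0 calls therefore do not show a lack of shift. No list was shown to shift beyond the spread between pools, and fry with the block was not run. For the other changes the cause was not tested. Leaving out 1 pool gave 0 calls in every comparison of sleep states and 23 to 34 list calls, where the lone pool is assumed to vary like those of other groups.

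Reversed values were Scn4b after deprivation in the hippocampal formation, from -0.79 to 0.13 over left-out pools (0.13 without the control pool of set 2) and 0.033 without set 2, and the striatal list there, from -0.376 to 0.0766 and 0.0931. Oligodendrocyte markers ranged from -0.273 to 0.0645 for deprivation (0.0645 without the control pool of set 1) and from -0.0529 to 0.239 for recovery against deprivation (-0.0529 without the recovery pool of set 1). In the recovery neocortex, inflammation ranged from -0.481 to 0.0418 and microglia from -0.408 to 0.261, both highest without the control pool of set 1. The heat shock median after deprivation in the hippocampal formation was -0.10 without the control pool of set 2, where camera's direction stayed upward (adjusted p = 0.896). The cause was not tested. Without the hippocampal pools of set 2 the 3 hippocampal counts were 0. Signal over background limits the dim 40% of probe sets, left out except where no filter was used, and most blood cell markers were among them.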

Other observations

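The choice and grouping of these values were made after they were seen, and the Sncg, Arc and Alas2 values come from the comparisons of sleep states. Sncg, the gamma-synuclein gene, was higher in recovery than in control and in deprivation in both structures, with log2 changes against control of 0.639 in set 1 and 1.22 in set 2 of the neocortex and of 0.911 and 1.40 in the hippocampal formation. Its change from control to deprivation was -0.17 (SE 0.24) in the neocortex and 0.13 (SE 0.24) in the hippocampal formation. Arc had a log2 change against control of 0.028 (SE 0.199) in the recovery neocortex and of 0.49 (SE 0.199) in the recovery hippocampal formation, each with adjusted p = 1.

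Alas2, the enzyme that starts haem synthesis in red cell precursors, had log2 changes against control of -1.19 in the recovery neocortex and -1.45 in the recovery hippocampal formation (SE 0.443), where its recovery signal was dim in the hippocampal formation (log2 4.11, under the filter level of 4.3). After deprivation it was at -0.18 and -0.55.

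The sets of rats differed in tissue markers. Choroid plexus markers were lower in set 2 than in set 1 by a median of -1.16 in each structure. The hippocampal minus neocortical median was 1.16 in set 1 and 1.12 in set 2 for hippocampal neuron markers, -0.571 and -0.174 for neocortical neuron markers and -1.41 and -1.53 for striatal markers.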
